A study of Saccharomyces cerevisiae with 270 samples.

How the data were processed

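Total RNA from Saccharomyces cerevisiae of the BF264-15D background was extracted with acid phenol, labelled with biotin and hybridised to Affymetrix yeast arrays, per the labels' protocols. The 270 arrays came from 9 cultures, each sampled over a time course after release from a G1 synchronization. The 9 cultures fell into 5 groups by strain and by the elutriation tag in the titles. The cdc28_whi5_stb1 group had 2 cultures of 33 arrays each, from 0 to 300 min. The cdc28_whi5_stb1_elutr group had 1 culture of 23 arrays up to 410 min and 1 of 19 arrays up to 310 min. The cdc16_cdc28_whi5_stb1 group had 2 cultures of 33 arrays each. The GAL_SIC1d3P group had 1 culture of 36 arrays from 10 to 360 min and 1 of 30 arrays from 10 to 300 min. The GAL_SIC1d3P_nrm1_yhp1_yox1 group had 1 culture of 30 arrays from 10 to 300 min.

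The deposited values were intensities on a linear scale, from 63.1 to 48341.1, for 5900 probe sets. The authors made them with the dChip model through affy 1.32.1 and normalized them jointly over 378 arrays, per the submitters' processing notes. The joint set held 108 arrays of earlier series, which were not used. A larger table of all 378 arrays was not used, because the value table held the 270 arrays of this series under their own names and 204 columns of the larger table carried other names. Median intensity per array lay between 2084.8 and 2333.5. No 2 arrays were identical, and the highest correlation of any 2 was 0.9994. For arrays of this kind the number of arrays and cultures limits the precision.

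Values were taken to log2 with no offset and no further normalization. Probe sets were named through GEO's platform annotation, with 12 symbols updated through the gene table of the R64 assembly. Of the 5900 probe sets, 5498 had 1 symbol, 0 had several and 402 had none, of which 265 were not Affymetrix controls. Of several probe sets for a gene, the one with the highest mean signal was kept. This concerned 47 genes, and their probe sets did not always vary together over the cultures, with a lowest correlation of -0.65 for RPL8A. The 5449 genes that remained were tested. The value table held no Schizosaccharomyces pombe probe sets, which had been planned as a background. In their place stood 23 control probe sets with no target in yeast RNA, whose mean log2 signal ran from 7.11 to 8.19, with a 95th percentile of 8.06. The mean of 160 genes lay at or below that level.

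The unit of replication was the culture, because the arrays of a culture follow each other in time and are not independent. The p-values measure the spread between cultures, which the series states to be biological replicates. Each culture gave 1 value per gene and measure. Mean level was the mean log2 signal over the times shared by the groups compared, 33 times for the cdc16 comparison, 12 for synchronization and 30 for nrm1 yhp1 yox1. Temporal variation was the log2 of the SD of the signal over those times. The late minus early change was the mean over 200 to 300 min minus the mean up to 90 min. The 0 min comparison used the first array of the 6 cultures that had one. Values were fitted with limma 3.58.1 under R 4.3.3 (lmFit with a mean per group, then eBayes), all 9 cultures in a fit, so that the group with 1 culture took its spread from the other groups and was assumed to vary like them. P-values were two-sided and adjusted by Benjamini-Hochberg over the 5449 genes, with a threshold of 0.05. An effect is given as a log2 difference with its SE. The SE uses the spread of all groups in the fit. It is too small for groups that vary more than the others, and too large for groups that vary less.

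Time courses were described without a test. A gene had a reproducible course where its signal spanned at least 1 log2 unit in both cultures of a group, from the 5th to the 95th percentile over time, and its profiles in the 2 cultures correlated at 0.7 or more. As a background, the genes that met the span in both cultures had their profiles in 1 culture shuffled among them. Those that still correlated at 0.7 or more were counted, over 100 draws. The share of the control probe sets was a further background. A gene had recurrent peaks where a running mean of 3 points had at least 2 local maxima of prominence 0.5 inside the course. A high at the first or last array was not counted. For the mean profile of a list the prominence was 0.3. These steps used python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

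The design, the measures, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Of 21 lists, 20 are reported. They were SBF targets, MBF targets, histones, Hcm1 targets, the CLB2 cluster, Mcm1 ECB genes, mating response, a-specific genes, alpha-specific genes, meiosis, heat shock, general stress, ribosomal proteins, ribosome biogenesis, galactose, respiration, gluconeogenesis and glyoxylate, phosphate, DNA damage and amino acid synthesis under Gcn4. Each was tested with limma's camera at a preset correlation of 0.01 and adjusted over all 21 lists, then again with an estimated correlation. The named genes are those in the strain names and, for each comparison, the 8 highest and 8 lowest called differences with no overlap between cultures (5 and 5 for a change within a group). To these come the 4 members with the smallest p of every list that camera called, and a fixed panel for the time courses: CLN2, CLN1, RNR1, CDC21, POL1, CLB5, SWI4, HCM1, HTA1, CLB2, CDC20, SWI5, CTS1, EGT2, ASH1, GAL1, FUS1 and HSP26.

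The linear fits were tested on simulated cultures in which 200 of the 5449 genes were changed. In the cdc16 comparison of mean level, 95.5% of the genes changed by 0.5 and 100% of those changed by 1 were recovered. For nrm1 yhp1 yox1 on mean level these shares were 87.9% and 100%, and for synchronization 87.9% and 100%. At 0 min they were 22.7% and 94%. For the late minus early change they were 74.2% and 98.5% in the cdc16 comparison and 57.6% and 97% in the nrm1 yhp1 yox1 comparison. For temporal variation they were 3% and 65.7%, and 0% and 35.8%. Between 0.06% and 0.34% of the genes left as they were passed the threshold. All simulated cultures were drawn with the same spread per gene. These shares thus cannot tell whether the lone culture or any group varies differently. The time course rule recovered every simulated pulse of 2 log2 units and none of 0.5, with 0 false calls. The unchanged genes were simulated as flat noise, so the 0 false calls give no error rate for real courses. For these the mismatched genes are the background. The rule for recurrent peaks found all genes with 2 simulated pulses of 1 log2 unit in the other groups and 59.5% of them in the elutriated group. Both pulses lay inside the course, so pulses at its start or end were not simulated.

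The alternatives tried were quantile normalization, an offset of 50, dim genes left out (below the control level or below a log2 of 10.5, which left out the dimmest genes), a fit of the compared cultures alone, the replicate number as a block, each culture left out in turn, all arrays in a fit with time as a factor and culture as a random effect, windows up to 60 and 240 to 300 min, and, for courses over time, a straight line removed and stricter limits. The filter at the control level, the arrays up to 15 min left out and the replicate numbers crossed between groups were added after the data were seen.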

Results

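RNA levels were measured on 270 arrays of 9 budding yeast cultures that were followed after release from a G1 synchronization. The strains carry mutations in the cyclin-dependent kinase CDC28, in WHI5 and STB1, which regulate G1 transcription, and in CDC16, a subunit of the anaphase-promoting complex, or carry a stabilised form of the kinase inhibitor SIC1 under a galactose promoter. The last is combined in 1 culture with deletions of NRM1, YHP1 and YOX1, which encode transcriptional repressors of G1 and early cell cycle genes. The cdc28 whi5 stb1 strain had 2 cultures of 33 arrays and 2 further cultures prepared by elutriation, of 23 and 19 arrays. The cdc16 cdc28 whi5 stb1 strain, here the cdc16 strain, had 2 cultures of 33 arrays. The GAL-SIC1Δ3P strain had 2 cultures of 36 and 30 arrays, and its nrm1 yhp1 yox1 derivative had 1 culture of 30 arrays. The cdc28 strains were grown in dextrose medium at 37 °C per the labels. For the GAL-SIC1Δ3P strains the labels name 2% of a sugar and no temperature. Titles without the elutriation tag name no synchronization method. The series design names elutriation and alpha-factor arrest. Median intensity per array lay between 2084.8 and 2333.5.

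The strain genes were read first, as a check of the labels. In the nrm1 yhp1 yox1 culture, mean log2 signal over the course was 7.22 for NRM1, 6.74 for YHP1 and 7.38 for YOX1, all below the 95th percentile of the control probe sets at 8.06. In the GAL-SIC1Δ3P cultures the same genes lay at 11.47 and 11.3, 11.4 and 11.07, and 11.91 and 11.76. STB1 lay between 6.96 and 7.41 in the 6 cultures with the stb1 mutation and between 9.17 and 9.67 in the 3 GAL-SIC1Δ3P cultures. SIC1 lay between 13.94 and 13.97 in the GAL-SIC1Δ3P cultures and between 9.64 and 10.13 in the others. WHI5 lay between 7.66 and 8.21 in every culture, near the control level, so it tells nothing of its mutation. Signals of CDC16 and CDC28 do not report on the alleles of these strains either.

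**Figure D1:**
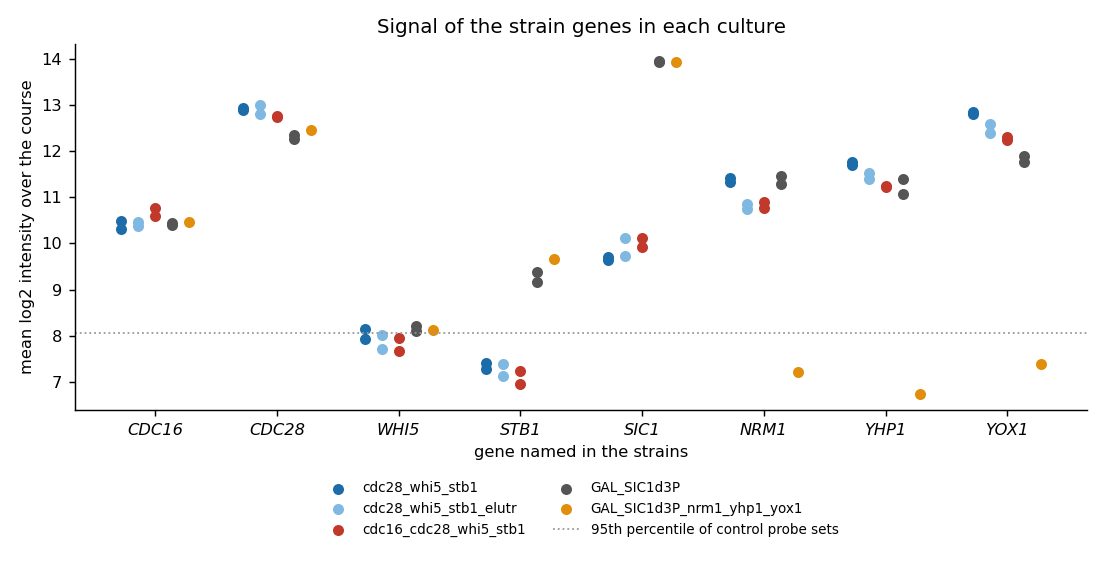
Mean log2 intensity over the time course for the 8 genes named in the strains, with 1 point per culture and colours for the 5 groups. The dotted line marks the 95th percentile of the control probe sets at 8.06, and NRM1, YHP1 and YOX1 fall below it only in the nrm1 yhp1 yox1 culture.

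The comparison of the nrm1 yhp1 yox1 culture with the GAL-SIC1Δ3P strain asks what these repressors do to cell cycle transcription while Clb-kinase activity is held down. Most listed genes of G1, DNA synthesis and mitosis were called higher in their absence. MCM5 and MCM3, subunits of the replicative helicase, rose by a log2 of 2.12 ± 0.10 and 2.04 ± 0.11 (SE, n = 1 against 2 cultures, here and below). RNR1, the large subunit of ribonucleotide reductase, rose by 1.32 ± 0.10, and CDC21, thymidylate synthase, by 1.11 ± 0.07. PRY1, a secreted sterol-binding protein, rose by 2.54 ± 0.09 and HOF1, a cytokinesis protein, by 2.57 ± 0.14, a lower bound because it lay below the control level in the GAL-SIC1Δ3P cultures. Over all genes 944 passed limma's test on mean level, 414 higher and 530 lower, and 85 of them changed at least by a factor of 2, with 67 of those higher.

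Of 28 measured MBF targets, which are G1 genes of DNA synthesis, 27 rose, and 27 did so adjusted over the list alone (camera adjusted p = 2.53e-24 and adjusted p = 0.057 with an estimated correlation). Their median was 0.76. Of 22 SBF targets, G1 genes of budding and cyclins, 17 rose, with 19 adjusted over the list alone, among them TOS2 by 1.18 ± 0.08 and CRH1 by 0.93 ± 0.07 (camera adjusted p = 3.5e-15 and adjusted p = 0.248 with an estimated correlation). Of 11 Mcm1 ECB genes, which are expressed at the M to G1 boundary and bound by Yhp1 and Yox1, 10 rose, and 10 adjusted over the list alone (camera adjusted p = 1.5e-13 and adjusted p = 0.0988 with an estimated correlation). The median of this list was 1.32. Of 22 genes of the mitotic CLB2 cluster, 15 rose, with 18 adjusted over the list alone, including DBF2 by 1.76 ± 0.11, MMR1 by 1.29 ± 0.10 and MYO1 by 1.10 ± 0.08 (camera adjusted p = 9.93e-14 and adjusted p = 0.248 with an estimated correlation). Among 7 a-specific genes 4 rose and 1 fell, with the same counts adjusted over the list alone, and MFA2, the a-factor precursor, rose by 1.87 ± 0.21 (camera adjusted p = 0.0282 and adjusted p = 0.435 with an estimated correlation). Of 11 DNA damage genes 3 rose and 1 fell, with the same counts adjusted over the list alone, including the kinase DUN1 at 0.90 ± 0.07 (camera adjusted p = 0.0496 and adjusted p = 0.306 with an estimated correlation). Of 20 Gcn4 targets 4 fell, with 7 adjusted over the list alone, and ARG1 of arginine synthesis was at -0.98 ± 0.10 (camera adjusted p = 0.035 and adjusted p = 0.656 with an estimated correlation). FDH1, formate dehydrogenase, was at -2.28 ± 0.23. Without GAL-SIC1Δ3P replicate 1 the test passed 507 genes, 280 higher and 227 lower, and without replicate 2 it passed 405, 232 and 173. With quantile normalization 352 were higher and 343 lower, so the majority of lower calls depends on the processing. The nrm1 yhp1 yox1 side rests on 1 culture, whose spread was assumed equal to that of the other groups.

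In the same comparison G1 genes differed most late in the course. From the first 90 min to 200 to 300 min, the change of CLB5, an S phase cyclin, was 1.32 ± 0.11 higher in the nrm1 yhp1 yox1 culture. That of the primase subunit PRI2 was 1.21 ± 0.09 higher, of CLB6 1.08 ± 0.08, and of SWI4, the DNA-binding subunit of SBF, 1.02 ± 0.09. In the GAL-SIC1Δ3P cultures SWI4 went from 10.82 ± 0.18 (SD, n = 2) at 25 to 60 min to 9.56 ± 0.08 at 245 to 300 min, and in the nrm1 yhp1 yox1 culture from 11.16 to 11.09. The difference in change passed the test in 772 genes, 409 higher and 363 lower. Of the 28 MBF targets 26 were higher, with 27 adjusted over the list alone (camera adjusted p = 5.74e-22 and adjusted p = 0.244 with an estimated correlation). Their median difference between the strains was 0.02 up to 20 min, -0.11 at 25 to 60 min, 0.66 at 65 to 120 min and 1.11 at 245 to 300 min. Of the 11 ECB genes 8 were higher, with 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.62e-06 and adjusted p = 0.364 with an estimated correlation). Of 12 Hcm1 targets, spindle and kinetochore genes, 4 were higher, with 9 higher and 1 lower adjusted over the list alone, including BUB1 at 0.85 ± 0.11 (camera adjusted p = 0.00103 and adjusted p = 0.388 with an estimated correlation). Of the 20 Gcn4 targets 12 were lower, with 15 adjusted over the list alone, and ARG1 was at -1.40 ± 0.12 (camera adjusted p = 2.59e-08 and adjusted p = 0.244 with an estimated correlation). Of 25 general stress genes 7 were higher, with 11 adjusted over the list alone (camera adjusted p = 0.0016 and adjusted p = 0.716 with an estimated correlation). The differences for MFA2, PRY1 and HSP150, a cell wall protein, were 3.33 ± 0.31, 2.94 ± 0.21 and 2.22 ± 0.11. Without GAL-SIC1Δ3P replicate 1 the count was 143 and without replicate 2 it was 314. It was 1185 with the compared cultures alone, 489 with genes below a mean log2 of 10.5 left out and 474 with windows up to 60 and 240 to 300 min.

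Variation over time was mostly lower in the nrm1 yhp1 yox1 culture. The SD over time of PRY1 differed by a log2 of -4.18 ± 0.22, that of NIS1, a bud neck protein, by -3.59 ± 0.23, and that of the pheromone pathway kinase FUS3 by -2.38 ± 0.22. The test passed 313 genes, 61 with higher and 252 with lower variation, while the median over all genes was -0.11. Of the 11 ECB genes 7 were lower and 1 higher, with 8 and 1 adjusted over the list alone (camera adjusted p = 9.49e-05 and adjusted p = 0.531 with an estimated correlation). Of the 7 a-specific genes 5 were lower, and 5 adjusted over the list alone (camera adjusted p = 0.000518 and adjusted p = 0.531 with an estimated correlation). Of 122 ribosomal protein genes 16 varied more, with 24 adjusted over the list alone, and the list's median was 0.73 (camera adjusted p = 3.8e-23 and adjusted p = 0.531 with an estimated correlation). The list mean of the ribosomal protein genes fell by 0.18 from early to late in this culture and by 0.02 and 0.03 in the GAL-SIC1Δ3P cultures. Without GAL-SIC1Δ3P replicate 1 only 4 genes passed, and 117 passed without replicate 2. With a straight line over time removed 121 genes passed, 8 with higher and 113 with lower variation, so most calls of higher variation ended, and at most 8 of the 16 ribosomal protein genes kept theirs.

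The comparison of the cdc16 strain with the cdc28 whi5 stb1 strain asks which part of the transcription program changes when the anaphase-promoting complex is impaired as well. Of the listed genes that were called, most mitotic ones were higher and those of the M to G1 boundary and of DNA synthesis lower. CHS2, the septum chitin synthase, rose by 1.14 ± 0.16 (SE, n = 2 against 2 cultures, here and below) and HOF1 by 1.08 ± 0.12, a lower bound because it lay below the control level in the cdc28 whi5 stb1 cultures. PRY1 was at -3.69 ± 0.08, MFA2 at -2.80 ± 0.17 and the pheromone-activated kinase inhibitor FAR1 at -1.59 ± 0.13. The helicase subunit MCM3 was at -1.10 ± 0.09, the S phase cyclin CLB6 at -0.85 ± 0.06 and the replication clamp POL30 at -0.78 ± 0.08. On mean level 302 genes passed the test, 100 higher and 202 lower, and 38 changed at least by a factor of 2, of which 33 were lower.

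Of the 22 CLB2 cluster genes 11 were higher and 1 lower, with 13 and 1 adjusted over the list alone (camera adjusted p = 3.73e-07 and adjusted p = 0.376 with an estimated correlation). Of the 28 MBF targets 17 were lower, with 25 adjusted over the list alone (camera adjusted p = 1.62e-20 and adjusted p = 0.0786 with an estimated correlation), and of the 11 ECB genes 9 were lower, with 10 adjusted over the list alone (camera adjusted p = 6.04e-13 and adjusted p = 0.103 with an estimated correlation). Of the 7 a-specific genes 3 were lower, with 5 adjusted over the list alone (camera adjusted p = 4.17e-05 and adjusted p = 0.207 with an estimated correlation). Of 7 galactose genes 4 were lower, with 6 adjusted over the list alone, and the epimerase gene GAL10 was at -1.22 ± 0.21 (camera adjusted p = 1.82e-05 and adjusted p = 0.316 with an estimated correlation). Of the 11 DNA damage genes 4 were lower, with 4 adjusted over the list alone (camera adjusted p = 0.0052 and adjusted p = 0.207 with an estimated correlation). None of the 122 ribosomal protein genes, 37 ribosome biogenesis genes, 27 respiration genes and 20 Gcn4 targets passed limma's test, and 0, 2, 2 and 3 of them had an unadjusted p under 0.05. The repressor genes NRM1, YHP1 and YOX1 were at -0.54 ± 0.11, -0.51 ± 0.09 and -0.56 ± 0.09, and these calls ended without any single culture, as did GAL10's without cdc16 replicate 1 and CHS2's without cdc16 replicate 1 or control replicate 2. The count was 79 without cdc16 replicate 1, 191 without cdc16 replicate 2, 102 without control replicate 1 and 96 without control replicate 2. In the fit of all arrays 797 genes were higher and 616 lower, so more calls were higher than lower there. All 259 genes called in both fits kept their direction.

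From early to late in the course, mitotic transcripts rose more in the cdc16 cultures than in the control. The late minus early change of CDC20, an activator of the anaphase-promoting complex, was 2.15 ± 0.20 higher than in the control and that of the mitotic exit kinase DBF2 2.27 ± 0.11. For histone genes this difference went the other way, with HTB2 at -1.63 ± 0.13 and HHT1 at -1.05 ± 0.07. The median change of the histone list was -0.06 in the cdc16 cultures and 0.86 in the control. The histone peaks of the cdc16 cultures, at 120 and 140 min, lay between the early and late windows. The difference passed the test in 584 genes, 305 higher and 279 lower. Of the 22 CLB2 cluster genes 20 were higher, and 20 adjusted over the list alone (camera adjusted p = 4.76e-22 and adjusted p = 0.241 with an estimated correlation). All 8 measured histone genes were lower, and 8 adjusted over the list alone (camera adjusted p = 7.22e-10 and adjusted p = 0.241 with an estimated correlation). Of the 11 ECB genes 9 were higher, and 9 adjusted over the list alone, including CDC6 at 1.62 ± 0.08 and MCM2 at 1.31 ± 0.10 (camera adjusted p = 2.39e-09 and adjusted p = 0.241 with an estimated correlation). Of 26 mating response genes 10 were higher, with 11 adjusted over the list alone (camera adjusted p = 3.39e-07 and adjusted p = 0.241 with an estimated correlation). Of the 28 MBF targets 6 were lower, and 6 adjusted over the list alone (camera adjusted p = 0.00181 and adjusted p = 0.499 with an estimated correlation). PHO3, an acid phosphatase, had the highest difference at 4.72 ± 0.36, and HPF1, a cell wall mannoprotein, the lowest at -2.89 ± 0.23. The median difference of the CLB2 cluster between the strains was -0.28 at 25 to 60 min and 1.16 at 185 to 240 min, and that of the histone genes 0.69 and -0.30. The count was 165 without cdc16 replicate 1, 228 without cdc16 replicate 2, 155 without control replicate 1 and 186 without control replicate 2. With the 4 compared cultures alone it was 1963, and with genes below a mean log2 of 10.5 left out it was 349.

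Variation over time was also higher for most CLB2 cluster genes. The SD over time differed by a log2 of 3.24 ± 0.22 for the daughter-specific glucanase gene DSE4, 2.76 ± 0.20 for HSP150, 2.52 ± 0.23 for MMR1 and 2.12 ± 0.21 for MOB1 of the mitotic exit network. For YND1, a Golgi nucleotidase, the difference was -2.45 ± 0.19 and for the stress regulator MSN2 it was -2.10 ± 0.21. The test passed 291 genes, 204 with higher and 87 with lower variation, while the median over all genes was 0.10. Of the 22 CLB2 cluster genes 17 varied more, with 19 adjusted over the list alone (camera adjusted p = 2.15e-17 and adjusted p = 0.136 with an estimated correlation). The count was 23 without cdc16 replicate 1, 65 without cdc16 replicate 2, 29 without control replicate 1 and 45 without control replicate 2. Fitted on its own 4 cultures alone, this comparison passed 959 genes.

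**Figure D2:**
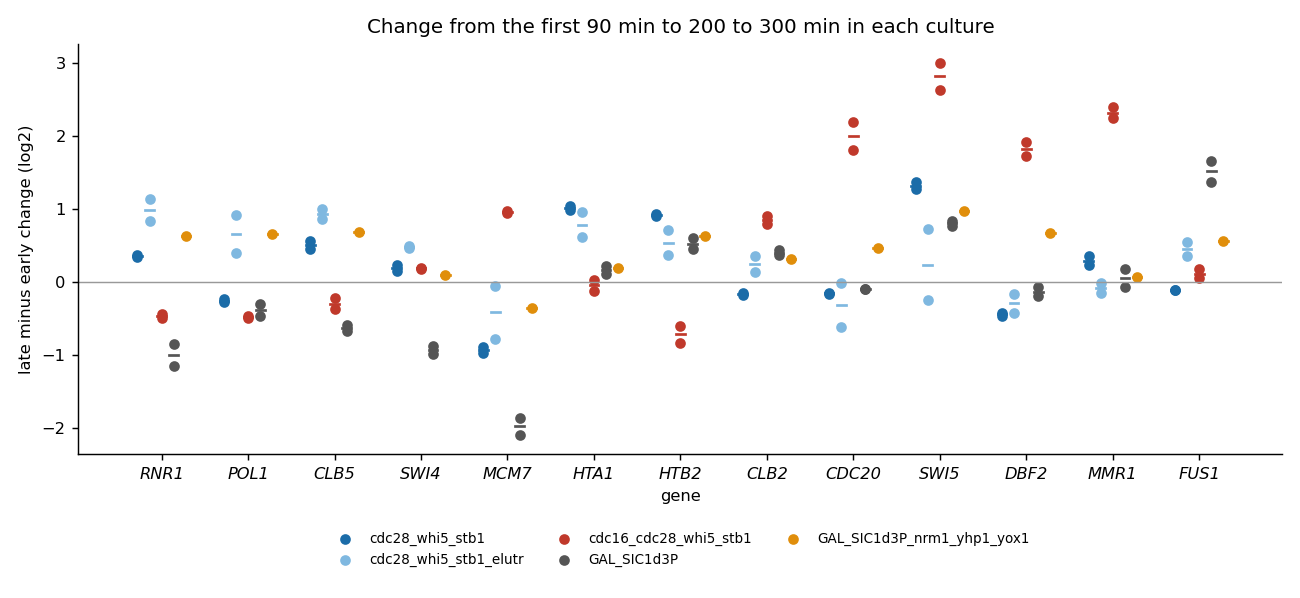
Late minus early change (log2, mean over 200 to 300 min minus mean up to 90 min) of 13 genes, with 1 point per culture, a bar at the group mean and colours for the 5 groups. CDC20 and SWI5 are highest in the cdc16 cultures, where HTB2 is lowest.

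The elutriated cultures of the cdc28 whi5 stb1 strain were set against those without the elutriation tag. The titles name the same mutations, but the preparation cannot be told from any other difference between these cultures. A strain difference at BAR1, described below, stays open. At 0 min mating response transcripts were lower and transcripts of SBF targets and of ribosome assembly higher in the elutriated cultures. FIG1 and PRM1, genes of mating cell fusion, were at -6.79 ± 0.10 and -5.87 ± 0.11 (SE, n = 2 against 2 cultures, here and below), and FUS1 at -4.78 ± 0.12. The G1 cyclins PCL1 and CLN1 were at 3.27 ± 0.19 and 3.06 ± 0.23 and the repressor gene YOX1 at 2.52 ± 0.22. DAN1 and TIR4, cell wall mannoproteins, were at 4.85 ± 0.63 and 4.29 ± 0.28, and the amino acid permease DIP5 at 4.64 ± 0.17. The differences of FIG1 and DAN1 are lower bounds, because the lower group lay below the control level. The test at 0 min passed 2078 genes, 1162 higher and 916 lower.

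Of the 26 mating response genes 25 were lower, and 25 adjusted over the list alone (camera adjusted p = 1.75e-22 and adjusted p = 0.199 with an estimated correlation). Of the 7 a-specific genes 6 were lower and 1, BAR1, was higher, with the same counts adjusted over the list alone (camera adjusted p = 0.000453 and adjusted p = 0.199 with an estimated correlation). Of the 27 respiration genes 23 were lower, with 24 adjusted over the list alone, including the succinate dehydrogenase gene SDH1 at -1.80 ± 0.11 (camera adjusted p = 4.78e-11 and adjusted p = 0.199 with an estimated correlation). Of 21 heat shock genes 18 were lower, with 19 adjusted over the list alone, including the chaperone genes STI1 at -1.42 ± 0.18 and SSA1 at -1.15 ± 0.15 (camera adjusted p = 6.7e-08 and adjusted p = 0.652 with an estimated correlation). Of the 37 ribosome biogenesis genes 21 were higher, with 24 adjusted over the list alone (camera adjusted p = 1.95e-06 and adjusted p = 0.652 with an estimated correlation). Of the 22 SBF targets 13 were higher and 2 lower, with 14 and 2 adjusted over the list alone (camera adjusted p = 0.00173 and adjusted p = 0.652 with an estimated correlation), and of the 8 histone genes 7 were higher, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0175 and adjusted p = 0.354 with an estimated correlation). Of the 28 MBF targets 3 were higher and 10 lower, with 3 and 11 adjusted over the list alone, and camera did not call the list (adjusted p = 0.0566). Of 16 genes of gluconeogenesis and the glyoxylate cycle 2 were higher and 8 lower, with 3 and 8 adjusted over the list alone, and camera did not call the list (adjusted p = 0.0562). Without control replicate 1 the count was 664 and without control replicate 2 it was 696.

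Over the 12 shared times fewer genes differed. BAR1, the secreted protease that degrades alpha-factor, was higher in the elutriated cultures by 3.98 ± 0.07, with its chromosomal neighbours YIL014C-A at 3.78 ± 0.13 and SNL1 at 3.16 ± 0.13. These are lower bounds, because in the cultures without the tag BAR1 and YIL014C-A lay below and SNL1 near the control level of 8.06. The transcript YGR109W-A of the retrotransposon Ty3 was at -4.35 ± 0.09, and the mating genes PRM2 and FUS1 at -2.22 ± 0.11 and -1.56 ± 0.08. The value of PRM2 is a bound as well, since it lay below the control level in the elutriated cultures. The test on mean level passed 377 genes, 225 higher and 152 lower, of which 23 changed at least by a factor of 2. Of the 26 mating response genes 20 were lower, with 22 adjusted over the list alone (camera adjusted p = 1.71e-24 and adjusted p = 0.0865 with an estimated correlation). Their median difference was -2.87 at 0 min, -0.58 at 65 to 120 min and -0.35 at 185 to 240 min. Of the 37 ribosome biogenesis genes 11 were higher, with 22 adjusted over the list alone, such as MAK16 at 0.57 ± 0.07 (camera adjusted p = 1.52e-08 and adjusted p = 0.165 with an estimated correlation). Of 4 alpha-specific genes 2 were higher, with 2 higher and 1 lower adjusted over the list alone, and camera did not call the list (adjusted p = 0.373). The call of MAK16 ended without either control culture, and the count was 29 without control replicate 1 (12 higher and 17 lower), 37 without control replicate 2 (14 and 23), 138 without elutriated replicate 1 and 1357 without elutriated replicate 2. Fitted on its own 4 cultures alone the comparison passed 28 genes, and 187 passed with the arrays up to 15 min left out.

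Within each strain the late minus early change was tested against 0. In the cdc28 whi5 stb1 cultures G1 cyclin and histone transcripts were higher late, with CLN2 at 1.58 ± 0.10 (SE, n = 2 cultures, here and below) and HHT1 at 0.91 ± 0.05, while the mating gene FIG1 was at -2.02 ± 0.08. The test passed 2705 genes in this group, 1377 higher and 1328 lower. All 8 histone genes rose, and 8 adjusted over the list alone (camera adjusted p = 5.71e-06 and adjusted p = 0.314 with an estimated correlation). Of 22 SBF targets 18 rose and 1 fell, with 19 and 1 adjusted over the list alone (camera adjusted p = 6.41e-07 and adjusted p = 0.314 with an estimated correlation). Of 21 heat shock genes 19 fell, and 19 adjusted over the list alone (camera adjusted p = 7.59e-08 and adjusted p = 0.314 with an estimated correlation). In the elutriated cultures CLN2 was at 1.51 ± 0.10 and the hexose transporter HXT4 at 2.66 ± 0.13, and 2919 genes passed, 1569 higher and 1350 lower. There 17 of 22 SBF targets rose, with 18 adjusted over the list alone (camera adjusted p = 1.54e-05 and adjusted p = 0.555 with an estimated correlation) and 15 of 28 MBF targets rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0102 and adjusted p = 0.726 with an estimated correlation). In the cdc16 cultures the mitotic regulator SWI5 was at 2.82 ± 0.20 and CHS2 at 2.73 ± 0.11, and 2668 genes passed, 1358 higher and 1310 lower. All 22 CLB2 cluster genes rose, and 22 adjusted over the list alone (camera adjusted p = 2.03e-15 and adjusted p = 0.399 with an estimated correlation). Of 28 MBF targets 23 fell, with 24 adjusted over the list alone (camera adjusted p = 2.58e-08 and adjusted p = 0.399 with an estimated correlation). In the GAL-SIC1Δ3P cultures MFA2 was at -3.83 ± 0.18, the helicase gene MCM3 at -1.65 ± 0.08 and the checkpoint kinase RAD53 at -0.91 ± 0.06, and 3099 genes passed, 1436 higher and 1663 lower. There 22 of 28 MBF targets fell and 1 rose, with 25 and 1 adjusted over the list alone (camera adjusted p = 3.57e-06 and adjusted p = 0.638 with an estimated correlation). Of 15 meiosis genes 9 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0159 and adjusted p = 0.638 with an estimated correlation). Of 12 phosphate genes 8 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0267 and adjusted p = 0.638 with an estimated correlation). Without replicates 1 and 2 in turn the count was 1029 and 981 in the cdc28 whi5 stb1 group and 1089 and 1345 in the cdc16 group, and it was 1908 in the GAL-SIC1Δ3P group without replicate 1. Without the arrays up to 15 min 1589 genes were higher and 1698 lower in the elutriated group, and 2047 of the 2152 genes called in both fits kept their direction. With the 2 elutriated cultures alone the count was 1426, and with genes below a mean log2 of 10.5 left out it was 1781 in the cdc28 whi5 stb1 group.

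The mean profile of each list was followed in each culture. In both GAL-SIC1Δ3P cultures the MBF targets had a peak at 50 min and the Hcm1 targets at 80 and 90 min. In the cdc16 cultures the MBF targets peaked at 40 min in both and the histone genes at 120 and 140 min, while the CLB2 cluster ranged over 2.14 and 1.99 log2 units. In the nrm1 yhp1 yox1 culture the MBF targets had no peak and were highest at 280 min. The ECB genes ranged over 1.57 and 1.5 in the GAL-SIC1Δ3P cultures and over 0.66 in that culture. The cyclin CLN2 went from 9.59 ± 0.14 (SD, n = 2) in the first 20 min to 12.14 ± 0.05 at 245 to 300 min in the GAL-SIC1Δ3P cultures, and HTA1 from 12.89 ± 0.01 to 14.04 ± 0.002 in the cdc28 whi5 stb1 cultures. Heat shock and general stress genes had a brief peak at 16 min in the cdc28 whi5 stb1 and cdc16 cultures and at 10 min in the elutriated cultures. Ribosome biogenesis genes followed at 64 min, and at 50 min in the elutriated cultures. General stress genes were also highest early, at 20 min, in the GAL-SIC1Δ3P and nrm1 yhp1 yox1 cultures, at 1.22, 1.23 and 1.03. These cultures were sampled only from 10 min, and the rule gave no peak there. No list had more than 1 peak in any culture, where a high at the first or last array does not count as a peak. The mating response of both cdc16 cultures was highest at 0 min, and its 1 counted peak was at 100 min.

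**Figure D3:**
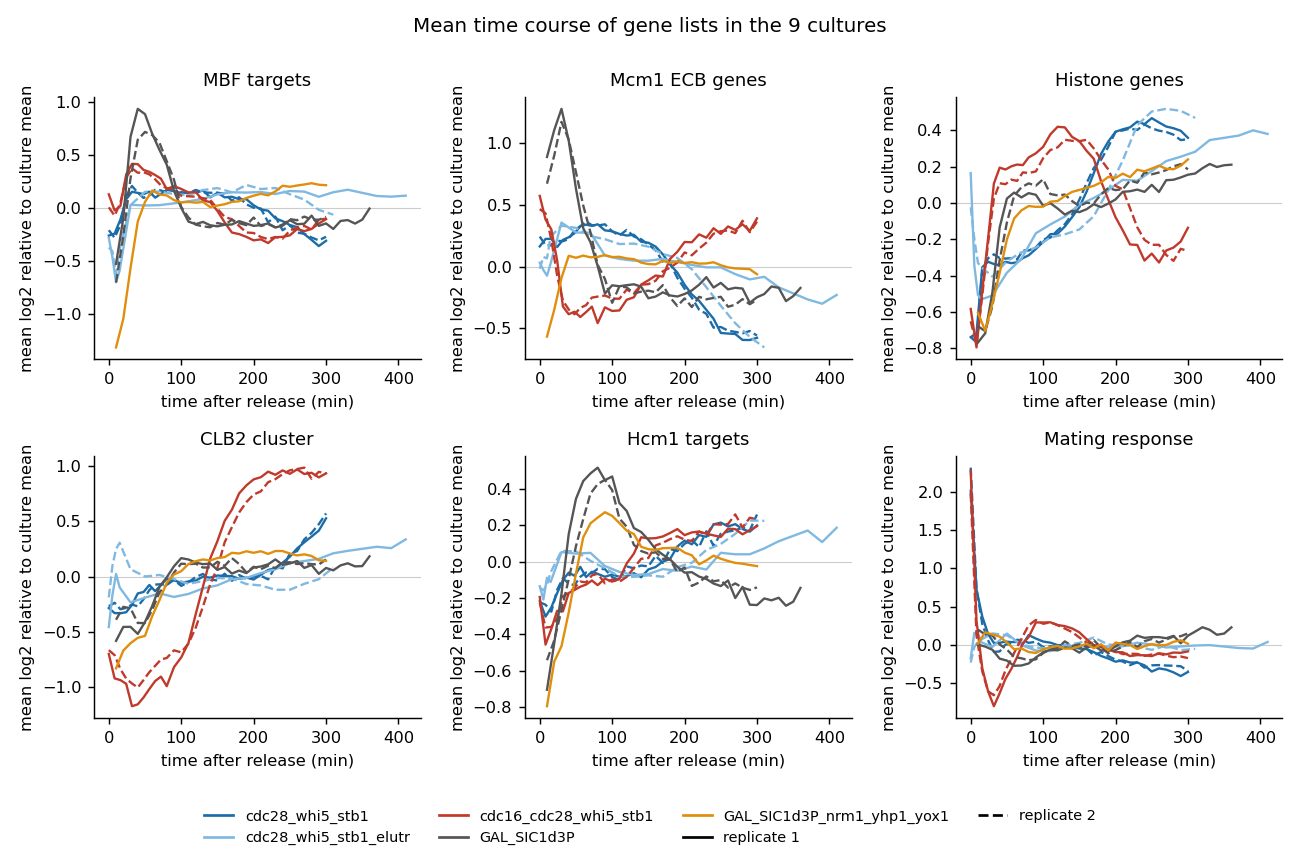
Mean log2 signal of 6 gene lists relative to each gene's mean in the culture, against time after release in min. Lines are the 9 cultures, coloured by group, with replicate 2 dashed. MBF targets come down after 50 min in the GAL-SIC1Δ3P cultures and not in the nrm1 yhp1 yox1 culture, and the CLB2 cluster goes up most in the cdc16 cultures.

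Reproducible courses were counted to see how much of the program changes in these cultures. They numbered 519 genes (9.5%) in the GAL-SIC1Δ3P group, 735 (13.5%) in the cdc16 group, 639 (11.7%) in the cdc28 whi5 stb1 group and 965 (17.7%) in the elutriated group. The span alone was met in both cultures by 529, 737, 643 and 1030 genes in the same order, so the correlation removed few. With profiles mismatched among these genes the mean counts were 121.8, 133.9, 119.2 and 171.9. Of the 23 control probe sets 1 met the rule in the cdc28 whi5 stb1 group and 0 in the other groups. Over the 4 groups 1429 genes met the rule in any group and 137 in all of them. Recurrent peaks inside the course were rare, with 35 genes that had them in at least 1 of the 9 cultures. Courses that began high, fell and rose again were not counted. In cdc16 replicate 1, CDC20 went from 9.99 at 0 min to 7.86 at 40 min and 10.57 at 260 min, with no peak by the rule. In both cultures of a group they occurred for YMR206W in the GAL-SIC1Δ3P strain, for ARO10, YAR009C and YJL027C in the cdc16 strain, and for ARO10, DIP5, SPI1 and SUC2 in the cdc28 whi5 stb1 strain. Of these 1, 3 and 4 genes, 0, 1 and 4 also met the rule for a reproducible course in that strain. In the elutriated group no gene had them in both cultures, where the rule found 59.5% of simulated genes with 2 pulses of 1 log2 unit. ARO10 encodes a decarboxylase of amino acid breakdown and SUC2 invertase. Of the 23 control probe sets 1 had recurrent peaks, in 1 cdc16 culture. Without the arrays up to 15 min the reproducible courses numbered 456 in the cdc16, 374 in the cdc28 whi5 stb1 and 322 in the elutriated group. With the span raised to 1.5 the counts were 158, 255, 183 and 358 in the order above, with a straight line over time removed they were 206, 526, 386 and 676, and with the peak prominence raised to 0.8 recurrent peaks were found for 5 genes.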

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

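The test of the normalization was chosen only after the result was seen, and the other tests were planned. The late minus early change differed between the cdc16 strain and the cdc28 whi5 stb1 strain in 584 genes, by a limma test of the difference itself. Without cdc16 replicates 1 and 2 and control replicates 1 and 2 in turn the count was 165, 228, 155 and 186. In 113 of the 584 genes the called changes went in opposite directions in the 2 strains. Of these, 72 rose in the cdc16 strain and fell in the control, and 41 fell in the cdc16 strain and rose in the control. The histone gene HTB2 had a change of -0.71 in the cdc16 strain and 0.92 in the control, CLB5 had -0.30 and 0.51, and the mannosyltransferase gene MNN1 had -1.44 and 0.78. Probe sets with no gene name stood outside the comparisons, and 80 of the 265 met the rule for a reproducible course in at least 1 group. So did 1429 of the 5449 named genes, a similar share, and 1 of the 23 control probe sets.

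The change also differed between the nrm1 yhp1 yox1 culture and the GAL-SIC1Δ3P strain, in 772 genes by the same kind of test. The count was 143 without GAL-SIC1Δ3P replicate 1 and 314 without replicate 2.

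The 39 MBF targets and ECB genes changed by a median of 0.92 more in the nrm1 yhp1 yox1 culture than in the GAL-SIC1Δ3P cultures. A delay shared by all genes of the culture is argued against by 456 genes outside the cell cycle lists. Their profiles matched the GAL-SIC1Δ3P profiles best at a delay of 0 min, with a correlation of 0.769 against 0.52 at 30 min. A delay of 30 min given to all these genes in a GAL-SIC1Δ3P culture was found as 30 min. Because the cell cycle genes were left out, the test cannot tell whether the cell cycle alone ran slower, and that stays open. A difference of the size seen between cultures of a group is argued against by the largest median difference between 2 cultures of a group, -0.1, and the between-array normalization by a median of 0.88 after quantile normalization. The loss of the 3 repressors, which the design names, stays open as a candidate explanation and was not tested apart from other differences of this culture. It is a hypothesis from 1 culture.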

How the results depend on the processing

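The fits of all arrays together, of the compared cultures alone and of the block and the leave-outs were planned, and the alternatives without arrays up to 15 min, with crossed numbers and with the filter at the control level were chosen after the data were seen. Of 133 alternative counts of tested results, 82 lay within 1.5 times the reported count, among them every count under quantile normalization, an offset of 50 and the filter at the control level. Of 6673 alternative values of named genes, 6181 kept direction and call, 432 lost the call, 57 gained it and 3 changed direction. No scaling moved the share of higher calls by over 10 percentage points. With a straight line over time removed, the share for cdc16 temporal variation was 82% against 70.1%. The direction with more calls turned in at least 1 alternative for every comparison of mean level and of the late minus early change, and for every late minus early change within a group. For nrm1 yhp1 yox1 on mean level it was 352 higher and 343 lower with quantile normalization, against 414 and 530, and for the elutriated late minus early change 1589 and 1698 without arrays up to 15 min, against 1569 and 1350, with 2047 of 2152 shared calls in the same direction. The mean log2 signal of the control probe sets ran up to 8.19. Signals below the control level of 8.06 cannot be told from background, and the mean of 160 genes lay at or below that level.

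The cause of the following moves was not tested. Leaving out dim genes or cultures leaves fewer genes or cultures to test, but counts moved both ways. With the compared cultures alone, cdc16 variation rose from 291 to 959, and synchronization on mean level fell from 377 to 28. Without genes below a mean log2 of 10.5, the cdc16 late minus early count was 349, the nrm1 yhp1 yox1 counts of mean level and late minus early change 549 and 489, and the cdc28 whi5 stb1 late minus early count 1781. With the compared cultures alone, counts were 959 for cdc16 variation, 1963 for cdc16 late minus early, 28 for synchronization on mean level, 205 and 1185 for nrm1 yhp1 yox1 variation and late minus early, and 1426 for the elutriated late minus early change. With all arrays, time as a factor and culture as a random effect, the mean level counts were 1413 for cdc16 (797 higher and 616 lower, against 100 and 202), 1259 for synchronization and 2769 for nrm1 yhp1 yox1. Windows up to 60 and 240 to 300 min gave 474 for nrm1 yhp1 yox1. Without arrays up to 15 min, synchronization on mean level gave 187, and reproducible courses numbered 456 in the cdc16, 374 in the cdc28 whi5 stb1 and 322 in the elutriated group. A span of 1.5 gave 158 for GAL-SIC1Δ3P, 255, 183 and 358 reproducible courses in the same order, and a straight line removed gave 206 for GAL-SIC1Δ3P, 386 for cdc28 whi5 stb1 and 121 genes for nrm1 yhp1 yox1 variation. A prominence of 0.8 left 5 genes with recurrent peaks. With the straight line removed, the cdc16 variation of HHT2 and HTA1 was 1.36 and 1.18 against -0.59 and -0.32, and the nrm1 yhp1 yox1 variation of RPS11A -0.038 against 1.69.

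With 1 culture left out, a lone culture being assumed to vary like the others, counts ran for cdc16 from 79 to 191 (mean level), 23 to 65 (variation) and 155 to 228 (late minus early). They ran for synchronization from 29 to 1357 on mean level and 664 to 2516 at 0 min, and for nrm1 yhp1 yox1 from 405 to 507, 4 to 117 and 143 to 314. For the late minus early change within groups they ran from 981 to 1029 in cdc28 whi5 stb1, 1089 to 1345 in cdc16, 3029 to 3542 in the elutriated and 1908 to 2071 in the GAL-SIC1Δ3P group.

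Same-numbered cultures are not stated to share anything, and their deviations from the group means correlated between -0.369 and 0.129 over the pairs of groups, so the numbers were not taken to pair the cultures. With the replicate block the counts were 224 for synchronization on mean level and 576, 197 and 447 for nrm1 yhp1 yox1. The other 8 counts stayed within 1.5 times, such as 218 for cdc16 on mean level. With crossed numbers the counts were 283, 183 and 489 for cdc16 and 207 and 1780 for synchronization.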

Other observations

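The tests of the galactose genes and of BAR1 and its neighbours below were chosen only after the results were seen. Changes within the strains also touched growth and stress genes. From early to late in the course, 24 of 37 ribosome biogenesis genes fell in the cdc28 whi5 stb1 cultures, with 27 adjusted over the list alone (camera adjusted p = 9.51e-07 and adjusted p = 0.396 with an estimated correlation). In the elutriated cultures 12 of 16 genes of gluconeogenesis and the glyoxylate cycle fell and 1 rose, with 12 and 1 adjusted over the list alone (camera adjusted p = 0.00161 and adjusted p = 0.531 with an estimated correlation). In the GAL-SIC1Δ3P cultures 14 of 21 heat shock genes rose and 3 fell, with 14 and 3 adjusted over the list alone (camera adjusted p = 0.00347 and adjusted p = 0.638 with an estimated correlation), and in the cdc16 cultures 18 of 21 fell, with 18 adjusted over the list alone (camera adjusted p = 8.91e-07 and adjusted p = 0.399 with an estimated correlation).

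Transcripts of the retrotransposon Ty3 were lower in the elutriated cultures, with YGR109W-A at -4.35 ± 0.09, YGR109W-B at -2.55 ± 0.16 and YIL082W-A at -2.47 ± 0.10 (SE, n = 2 against 2 cultures). UBC13, a ubiquitin-conjugating enzyme, was higher there by 2.06 ± 0.08. The 2 elutriated cultures lay apart in PHO84, the phosphate transporter, with a mean log2 signal over the shared times of 12.98 in replicate 1 and 8.55 in replicate 2, against 8.53 and 8.84 in the cultures without the tag. PHO84 was chosen after its values were seen.

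The galactose genes GAL1, GAL2, GAL7 and GAL10 were called lower in the cdc16 strain, with a median of -1.23, although the labels name dextrose medium for both strains. At 0 min GAL1 lay at 14.97 in the cdc28 whi5 stb1 cultures, 14.98 in the cdc16 cultures and 14.75 in the elutriated cultures. The galactose genes fell after release in these groups, with list medians of -1.51, -1.40 and -1.85 from early to late. The labels state no change of medium, and the reason for the fall was not tested, so a lower mean level here describes a lower course of that fall. The between-array normalization is argued against by a median of -1.24 after quantile normalization. A difference already present at release and one that arose later cannot be told apart. The 3 called genes other than GAL1 differed by a median of -0.14 at 0 min and by -1.22 over the course, but GAL7 and GAL10 lay above the 95th percentile of all signals at 0 min, 14.08, where a difference may be compressed, and replicates of GAL2, near that percentile, lay up to 0.51 apart. The dimmer list members GAL3 and GAL80, which were not called, differed by -0.43 and -0.2 at 0 min and by -0.26 and -0.32 over the course, and both were chosen after their values were seen. The cdc16 mutation, which the design names, stays open and untested, and the calls of all 4 genes ended without cdc16 replicate 1, those of GAL2 and GAL7 also without control replicate 1 and that of GAL2 also without cdc16 replicate 2.

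BAR1, SNL1 and YIL014C-A, neighbours on the chromosome, were higher in the elutriated cultures, where BAR1 lay at 11.13 and 11.36 against 6.86 to 7.59 in the other 7 cultures. The normalization is argued against by a ratio of 1.01 of the quantile normalized to the reported difference. A state that had faded by 200 to 290 min is argued against, because the smallest difference of any elutriated culture from any cdc28 whi5 stb1 culture without the tag was still 2.83 then, and at the control level it can only be too small. A state that fades in part and a strain difference at this locus cannot be told apart. The median ratio of late to early difference was 1.14, but both differences are lower bounds, because BAR1 and YIL014C-A lay below and SNL1 near the control level of 8.06 in the cultures without the tag, and the early one comes from 1 time. The 3 genes made a run of 3 adjacent genes changed in the same direction among the 23 that changed at least by a factor of 2, and 1 of 10000 shuffles of gene order had as long a run (p = 0.0002), but the test was chosen after the genes were seen to be neighbours. For VID28 beside them, which was lower, the difference went from -3.61 at 0 min to -1.55 late, a ratio of 0.43, which is consistent with a state that fades in part.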
